A study of Mus musculus with 18 samples.

How the data were processed

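RNA abundance was measured with Affymetrix Mouse Genome 430 2.0 arrays in CD23-positive B lymphocytes from the spleens of C57BL/6J mice. CD23 is the low-affinity receptor for IgE and is carried by follicular B cells. Mice received vehicle or PF-303, an inhibitor of BTK, the kinase that passes the signal of the B-cell receptor to phospholipase C. The mice were then given PBS or an antibody against IgD, which crosslinks the B-cell receptor in vivo. The drug was given 2 h before the antibody and cells were collected 2 h after it. Total RNA was purified on columns with DNase treatment, and 150 ng per sample was converted to biotinylated cRNA with the GeneChip 3' IVT Express kit, which copies transcripts from their 3' ends.

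The deposited values are MAS5 signals, an intensity per probe set on a linear scale, which the authors produced with MAS5 as named in the submitters' processing notes. No version or setting of MAS5 is given in the sources used here. MAS5 sets the signal of the perfect-match probes against that of the mismatch probes, which makes values near the background noisy. The 18 arrays had the same 2%-trimmed mean of 99.9, so each array had been scaled to one common level. Such scaling removes any difference in total RNA per cell between groups, and a gene is then higher or lower relative to the rest of the array. No detection calls were used here, and no further normalization between arrays is stated. The table held 45101 probe sets, of which 64 were controls. The platform annotation gave 1 gene symbol to 34945 probe sets, several symbols to 932 and none to 9160, and the named probe sets covered 18193 genes. Symbols were looked up through their gene identifiers in a RefSeq gene table of the GRCm38.p6 assembly, in which 204 probe sets had no match and kept the platform's symbol. That table served for names only, and no positions in the genome are given because the probe sets carry none here.

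Samples were grouped by the labels into PBS with vehicle (n = 4), anti-IgD with vehicle (n = 4), PBS with PF-303 (n = 5) and anti-IgD with PF-303 (n = 5). The labels number the samples within a group but do not state that each came from a separate mouse, so the p-values measure the spread between these samples, which may be in part technical. Replicate numbers recur in different groups without pairing the samples, and an alternative fit with the number as a block was run. No arrays held identical values. The standard deviation of the log2 differences between 2 arrays was at least 0.238, with a median of 0.311 within groups. For arrays, precision is limited by their number. The median standard error of a log2 fold change was 0.129 for anti-IgD in vehicle-treated mice and 0.174 for the difference between the 2 responses.

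Signals were taken as log2(signal + 16). Adding 16 damps the noise of low signals and also makes the fold changes of weakly expressed genes smaller than the ratio of their signals. Control probe sets were left out. Probe sets were kept when their signal exceeded 15.2, the median of all values, in at least 4 arrays. For each gene the probe set with the highest mean over the 18 arrays was used, which left 11106 genes. Linear models were fitted with limma 3.58.1 and statmod 1.5.0 in R 4.3.3 (lmFit, then eBayes with a mean-variance trend), with 1 mean per group and all 18 arrays in 1 fit. The 5 contrasts were anti-IgD against PBS in vehicle-treated mice, PF-303 against vehicle in anti-IgD-treated mice, PF-303 against vehicle in PBS-treated mice, anti-IgD against PBS in PF-303-treated mice, and the difference between the 2 responses to anti-IgD (interaction). Tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method over genes within each contrast. A gene was called at an adjusted p under 0.05. Errors of fold changes are standard errors of the limma fit, and errors of signals are standard deviations between arrays.

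The comparisons, their tests, the gene lists and the rule for naming genes were set before the data were examined. There were 15 pathway lists: immediate early genes, MAPK feedback genes, NF-kB target genes, calcium-NFAT genes, B-cell activation surface and secreted proteins, ribosome biogenesis, MYC-linked growth metabolism, FOXO and quiescence genes lowered by PI3K signalling, B-cell receptor signalling components, BCL2 family, heat shock and chaperones, unfolded protein and integrated stress response, interferon-stimulated genes, cell cycle progression, and readouts of TLR and cytokine signals. There were 13 marker lists: follicular B, marginal zone and B1 B, germinal centre B, plasma cell, T cell, NK cell, macrophage and monocyte, neutrophil, dendritic cell, erythroid, platelet and megakaryocyte, mast cell and basophil, and stromal and endothelial cells. Lists share genes, as with Irf4 on the NF-kB and calcium-NFAT lists. Each list was compared with all other genes by camera with a preset inter-gene correlation of 0.01, and again with a correlation estimated per list. The fry rotation test asked whether a list's genes moved, on balance, in 1 direction. List p-values were adjusted over the 28 lists of a contrast. Named genes are the 8 largest rises and 8 largest falls of the first 2 contrasts and the 4 and 4 of the others, among called genes whose arrays do not overlap between the groups (a condition not applied to the interaction), passing over clone and predicted symbols. These were known by the form of the symbol, which also passed over some known genes whose symbol is a letter from A to E followed by a digit, so a gene left unnamed can have a larger change than a named one. Up to 2 members per direction with the lowest p were added for each pathway list, together with the 2 markers of highest mean signal per cell type and 15 genes followed in every contrast (Btk, Egr1, Egr2, Nr4a1, Myc, Cd69, Cd86, Cd83, Ccl3, Ccl4, Nfkbia, Nfkbid, Irf4, Klf2 and S1pr1). A gene named outside this rule is marked as chosen after its values were seen.

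The share of the anti-IgD response kept under PF-303 was the log2 fold change in PF-303-treated mice divided by that in vehicle-treated mice. Its median was taken over genes called in vehicle with a change of at least 2-fold, with a jackknife over arrays for the error. For a list, the share was the sum of the fold changes of its called members under PF-303 divided by their sum in vehicle. Each response was set against its own PBS group and, as an alternative chosen after seeing the results, the level under PF-303 with anti-IgD was set against the PBS level of vehicle-treated mice. The fits were tested on simulated data drawn from the real means and spreads of the 11106 genes, with 200 genes changed at a time. At a log2 change of 1, the share of changed genes recovered was 91.0% for anti-IgD in vehicle-treated mice, 94.0% for PF-303 in anti-IgD-treated mice, 95.0% for PF-303 in PBS-treated mice, 96.5% for anti-IgD in PF-303-treated mice and 77.5% for the interaction. At 0.5 these shares were 53.0%, 56.5%, 53.5%, 53.0% and 28.5%. In the simulation a shifted list was called, 0 of 20 unshifted lists were called, and a share of 60% put into the data was found as 59.3%. Each gene was drawn independently of the others there. The simulation therefore does not test list calls where the genes of a list vary together, as they do in real data.

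Alternatives covered offsets of 1 and 64, no filter and a filter at the 70th percentile, quantile normalization, every probe set tested, the mean of a gene's probe sets, no variance trend, a robust variance prior, array weights, fits of only the groups compared, a replicate block, the row and the column of a position code in the sample descriptions that reads like a plate well, each array left out in turn, and stricter thresholds. Further alternatives were chosen after seeing the data. Signals of the spike-in controls, bacterial and phage transcripts that the array platform uses as added controls, differed several-fold between arrays, which led to a spike-in covariate and to a fit without the arrays of high spike-in signal. A fit without the 2 arrays of highest 3' to 5' ratio of Gapdh was made, and a fit with each array shifted to one median (median centring) because the median log2 fold change of all genes was not 0. Probe sets with no symbol or several symbols were left out of the comparisons and are described at the end.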

Results

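The response of mature B cells to receptor crosslinking in vivo, and its dependence on BTK, was followed in CD23-positive splenic B cells of C57BL/6J mice. Mice received vehicle or the BTK inhibitor PF-303, and 2 h later PBS or an antibody against IgD, the receptor isotype carried by mature follicular B cells. Cells were taken 2 h after the antibody. RNA was measured on 18 arrays, 4 from each vehicle group and 5 from each PF-303 group, and 11106 genes passed the filter on signal. The labels do not state that every sample came from a separate mouse, so p-values measure the spread between samples.

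Anti-IgD set the arrays apart more than the inhibitor did. The first principal component held 53.4% of the variance and ordered the groups by stimulation. Its mean was -27.2 ± 1.24 (SD, n = 5) for PBS with PF-303, -18.8 ± 2.43 (n = 4) for PBS with vehicle, 11.5 ± 1.92 (n = 5) for anti-IgD with PF-303 and 38.4 ± 1.93 (n = 4) for anti-IgD with vehicle. The stimulated cells of PF-303-treated mice thus lay between the resting cells and the stimulated cells of vehicle-treated mice. The second component held 8.95% of the variance and had a correlation of 0.81 with the spike-in signal. On it, arrays of anti-IgD with vehicle lay from -11.2 to -4.85 and those of anti-IgD with PF-303 from 1.98 to 22.3. The 2 stimulated groups were thus also apart along a component that correlates with the spike-in signal. In 6 arrays the spike-in controls had more than 2 times their median signal over all arrays: replicates 3 and 4 of PBS with vehicle (2.39 and 3.74 times), replicates 3 and 4 of PBS with PF-303 (3.35 and 2.48) and replicates 1 and 3 of anti-IgD with PF-303 (2.93 and 2.40). In the group given anti-IgD and vehicle this ratio lay between 0.522 and 1.15.

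**Figure D1:**
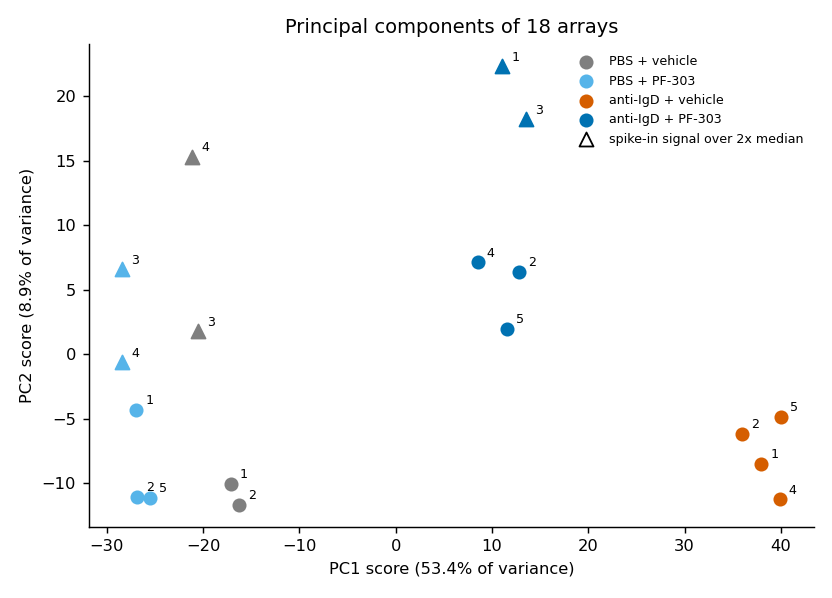
Principal components of log2(signal + 16) over 11106 genes, 1 point per array (axes in component units), coloured by group and numbered by replicate, with triangles for the 6 arrays of high spike-in signal. Groups separate along the first component (53.4% of variance), from -27.2 for PBS with PF-303 to 38.4 for anti-IgD with vehicle.

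In vehicle-treated mice, anti-IgD raised early response genes of antigen-receptor signalling. Signals of Egr2, a zinc finger transcription factor induced through calcium and ERK signalling, went from 62.7 ± 19.8 (SD, n = 4) to 2599 ± 321 (n = 4), a log2 fold change of 5.08 ± 0.14 (SE; adjusted p = 1.5e-16). The orphan nuclear receptors Nr4a3 (4.57 ± 0.19) and Nr4a1 (3.49 ± 0.15), the transcriptional repressor Gfi1 (4.01 ± 0.13) and the small MAF protein gene Maff (3.29 ± 0.19) rose with it. The chemokine genes Ccl4 (3.72 ± 0.20) and Ccl3 (2.58 ± 0.19), whose products draw T cells and myeloid cells, the kinase gene Plk2 (3.35 ± 0.16) and Slc7a5 (3.24 ± 0.28), which encodes a chain of a transporter of large neutral amino acids, rose as well. The fold changes of genes with low PBS signals depend on the added 16, and those of Ccl3 and Maff were 4.16 and 5.10 with an offset of 1 and 1.40 and 1.95 with 64. Myc, a driver of cell growth, went from 523.8 ± 105 to 2883 ± 138 (2.44 ± 0.13; adjusted p = 2.8e-12). Irf4, a regulator of B-cell differentiation, rose by 2.14 ± 0.12 and Egr1 by 2.94 ± 0.17, and the activation markers Cd86 (1.92 ± 0.10), Cd83 (1.69 ± 0.13) and Cd69 (1.38 ± 0.16) rose too.

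Falls were found for Rflnb (-2.59 ± 0.16, adjusted p = 1.8e-11), Trim7 (-2.03 ± 0.13), the kinesin gene Kif21b (-2.02 ± 0.18), Neurl3 (-2.01 ± 0.15), Kbtbd11 (-1.98 ± 0.11), the sphingosine-1-phosphate receptor gene S1pr4 (-1.97 ± 0.10), Traf5 (-1.90 ± 0.09), which encodes an adaptor of TNF receptors, and Rasa3 (-1.81 ± 0.10), which encodes a GTPase-activating protein. Klf2, a transcription factor of quiescent lymphocytes, went from 2260 ± 145 to 799.9 ± 79.9 (-1.48 ± 0.12), and S1pr1, the receptor that guides exit from lymphoid tissue, went from 575.3 ± 89.5 to 277.2 ± 45.3 (-1.01 ± 0.12; adjusted p = 2.1e-07). Btk itself fell by 0.53 ± 0.08 on the log2 scale (adjusted p = 4.4e-06). Nfkbia, which encodes an inhibitor of NF-kB, had a value of 0.06 ± 0.11 (adjusted p = 0.68) at the probe set used.

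**Figure D2:**
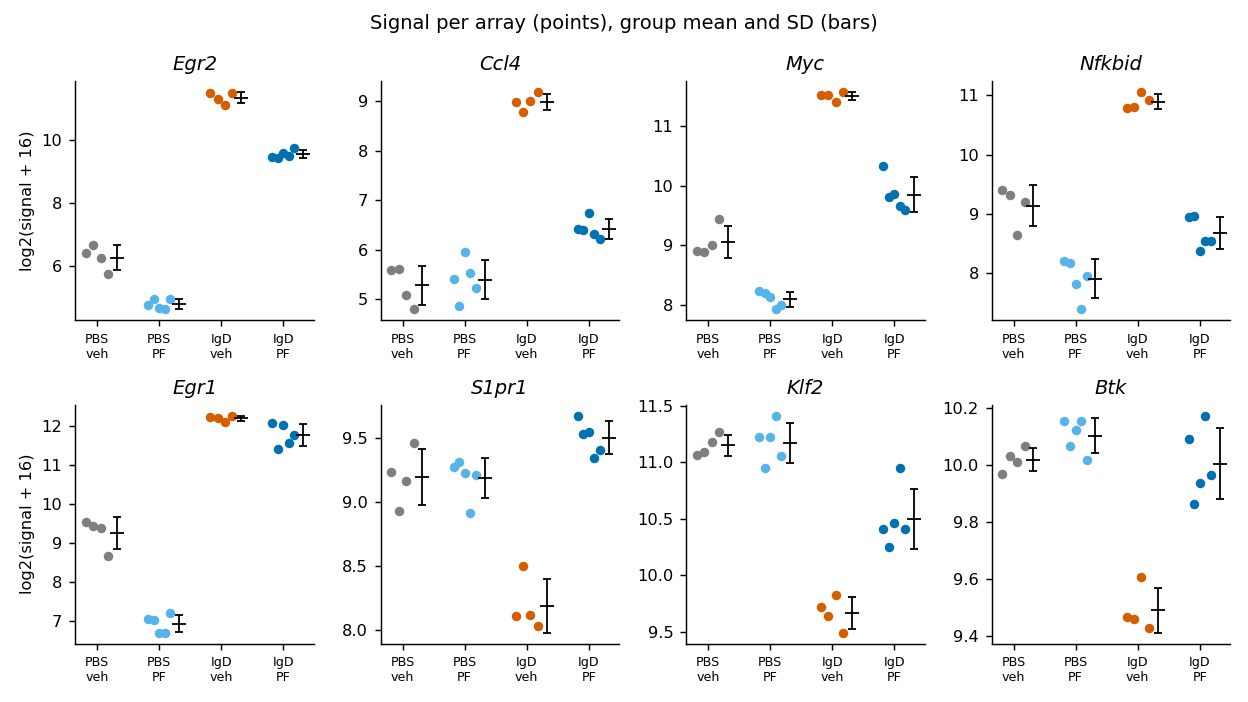
Signals of 8 genes as log2(signal + 16), 1 point per array, in the 4 groups (n = 4, 4, 5 and 5), with bars for the mean and SD. Egr2, Ccl4, Myc and Nfkbid rose with anti-IgD and reached lower levels under PF-303, while S1pr1 and Klf2 fell in vehicle-treated mice by 1.01 and 1.48 on the log2 scale.

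Growth genes moved together. Of 49 measured genes of ribosome biogenesis, 48 rose and 0 fell, with a median log2 fold change of 1.17. Examples are Gnl3, which encodes a nucleolar GTPase (2.04 ± 0.08), and Nolc1, which encodes a nucleolar phosphoprotein (2.00 ± 0.09). Of 36 genes of MYC-linked growth metabolism, 28 rose and 1 fell, among them the hexokinase gene Hk2 (2.21 ± 0.10) and the spermidine synthase gene Srm (2.09 ± 0.10), while Tfam, a factor of mitochondrial DNA, fell by 0.27 ± 0.07, a call lost after shifting arrays to one median (-0.11). Of 26 immediate early genes, 14 rose and 4 fell. The falls included Klf6 (-0.65 ± 0.09) and the antiproliferative gene Btg2 (-0.46 ± 0.10). The 3 lists were higher against the other genes in camera with an estimated correlation (adjusted p = 3.4e-06 for ribosome biogenesis and 3.2e-04 for each of the others).

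Lists of single signalling routes moved both ways within themselves. Of 24 NF-kB target genes, 15 rose and 6 fell. Rel, an NF-kB subunit (1.93 ± 0.09), and Nfkbid, an atypical inhibitor of NF-kB (1.76 ± 0.17), rose, whereas Bcl3 (-1.28 ± 0.14) and the cytokine gene Lta (-0.81 ± 0.10) fell. Of 17 calcium-NFAT genes 8 rose and 6 fell, among the latter the calcineurin subunit genes Ppp3ca (-0.64 ± 0.09) and Ppp3cc (-0.59 ± 0.08). Of 15 MAPK feedback genes 7 rose, as Spred1 did (0.89 ± 0.17), and 1 fell, the ERK phosphatase gene Dusp6 (-0.60 ± 0.10). With an estimated correlation the adjusted p was 0.030 for NF-kB, 0.030 for calcium-NFAT and 0.019 for MAPK feedback, each with the list higher.

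Genes of the resting state and of the receptor pathway mostly fell. Of 31 FOXO and quiescence genes, 20 fell and 4 rose (21 fell when adjusted over the list alone), with a median of -0.76 and an adjusted p of 0.021 with an estimated correlation. The cell cycle inhibitor gene Cdkn1b (-1.60 ± 0.09) and Ypel3 (-1.49 ± 0.07) fell, while Irs2, which encodes an adaptor of the insulin receptor (2.88 ± 0.13), and Trib2 (1.01 ± 0.11) rose. Of 35 B-cell receptor signalling components, 20 fell and 5 rose. The kinase gene Syk (-1.56 ± 0.10) and the ubiquitin ligase gene Cblb (-1.18 ± 0.09) fell, and the kinase gene Fyn (2.01 ± 0.14) and the PI3K adaptor gene Pik3ap1 (1.36 ± 0.16) rose. The camera call of this list (adjusted p = 0.045) was lost with an estimated correlation (adjusted p = 0.54 with an estimated correlation). It was also lost without replicate 3 or 4 of PBS with vehicle, replicate 2 or 4 of anti-IgD with vehicle or the 6 arrays of high spike-in signal, and with a replicate block or spike-in covariate (medians from -0.42 to -0.31). Of 25 activation surface and secreted proteins 13 rose and 9 fell, with the oxysterol receptor gene Gpr183 higher (1.83 ± 0.09) and the TACI gene Tnfrsf13b (-1.11 ± 0.11) and Cd40 (-0.86 ± 0.12) lower. Its adjusted p was 0.0011, and 0.050 with an estimated correlation, above the threshold.

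Together 1926 genes were higher and 3392 lower with anti-IgD in vehicle-treated mice, and 392 and 401 of them changed at least 2-fold. The median log2 fold change of all genes was -0.13. After shifting every array to one median, 2772 genes were higher and 2179 lower, so the balance of rises and falls depends on how arrays are put on one scale.

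Under PF-303, stimulated cells had less RNA of many genes that anti-IgD had raised. Nr4a3 (-3.03 ± 0.18, adjusted p = 3.8e-10), Ccl4 (-2.57 ± 0.19), Ccl3 (-1.79 ± 0.18) and Egr2 (-1.80 ± 0.13) were lower than in stimulated cells of vehicle-treated mice. The size for Ccl3 depends on the offset (-2.31 with 1 and -1.09 with 64). Signals of Ccl4 were 494.5 ± 59.96 with vehicle (n = 4) and 69.98 ± 12.3 with PF-303 (n = 5). Nfkbid (-2.22 ± 0.16) and Nfkbiz (-1.71 ± 0.12), both atypical IkB proteins, the histone demethylase gene Kdm6b (-1.67 ± 0.14) and Bend3 (-1.72 ± 0.09) completed the largest falls. Myc was lower by 1.65 ± 0.13, at 924.1 ± 205 against 2883 ± 138, and Nr4a1 by 1.25 ± 0.14. Egr1 differed less, at -0.43 ± 0.16 (adjusted p = 0.042), and Cd83 had a value of -0.20 ± 0.12 (adjusted p = 0.25). Cd69 (-0.82 ± 0.15), Irf4 (-0.49 ± 0.12) and Cd86 (-0.46 ± 0.09) were lower, and Nfkbia was lower by 0.29 ± 0.11 (adjusted p = 0.044). The Egr1 call was lost on leaving out any one array of anti-IgD with vehicle or replicate 2, 4 or 5 of anti-IgD with PF-303 (values from -0.46 to -0.34). The Nfkbia call was lost without replicate 1, 2 or 5 of anti-IgD with vehicle, replicate 1 of PBS with PF-303, or replicate 2, 3, 4 or 5 of anti-IgD with PF-303 (-0.30 to -0.25).

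Kctd14 was higher with PF-303 in stimulated cells (1.49 ± 0.10, adjusted p = 6.3e-10), with signals of 739.2 ± 64.2 against 253 ± 16.8. Emp3 (1.34 ± 0.13), S1pr1 (1.31 ± 0.11), Ddit4, which encodes an inhibitor of mTORC1 (1.27 ± 0.17), Rell1 (1.26 ± 0.10), Gpat3, which encodes an enzyme of glycerolipid synthesis (1.24 ± 0.11), Insl6 (1.19 ± 0.16) and Tmem108 (1.17 ± 0.11) were higher too. Klf2 was higher by 0.83 ± 0.12, with signals of 1447 ± 293 against 799.9 ± 79.9, and Btk was higher by 0.52 ± 0.07 (adjusted p = 1.0e-05).

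The gene lists moved mostly against the direction of anti-IgD. Of 49 ribosome biogenesis genes 46 were lower (48 when adjusted over the list alone), as were Nolc1 (-1.09 ± 0.08) and Nop16 (-0.99 ± 0.08). Of 36 genes of MYC-linked growth metabolism 25 were lower, with Hk2 at -1.20 ± 0.10 and the transferrin receptor gene Tfrc at -1.17 ± 0.10. Of 24 NF-kB targets 16 were lower, Rel by 1.34 ± 0.09, and 3 higher, with Lta at 0.53 ± 0.10. Of 26 immediate early genes 11 were lower (12 when adjusted over the list alone) and 3 higher, with Klf6 at 0.82 ± 0.09 and Jun at 0.46 ± 0.11. Of 17 calcium-NFAT genes 7 were lower and 2 higher (8 and 3 when adjusted over the list alone), and Ppp3ca was higher by 0.45 ± 0.08. These 5 lists were lower with an estimated correlation (adjusted p = 3.5e-06, 6.8e-04, 0.0017, 6.8e-04 and 0.018 in this order).

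Quiescence genes were higher: of 31 FOXO and quiescence genes 17 were higher and 2 lower, with Cdkn1b at 1.06 ± 0.09 (adjusted p of the list 0.0040 with an estimated correlation). Of 35 receptor signalling components 19 were higher and 3 lower (22 higher when adjusted over the list alone). The exchange factor gene Rasgrp3 (0.91 ± 0.10) and the phospholipase gene Plcg2 (0.62 ± 0.08) were higher, and Vav3, another exchange factor gene (-0.99 ± 0.13), and Fyn (-0.55 ± 0.13) were lower. The adjusted p of this list was 3.2e-04, and its call was lost with an estimated correlation (adjusted p = 0.14 with an estimated correlation). MAPK feedback genes had 2 higher, Dusp6 (0.88 ± 0.09) and the urokinase receptor gene Plaur (0.78 ± 0.10), and 2 lower of 15 (2 and 0 when adjusted over the list alone), and activation surface proteins had 8 higher and 9 lower of 25 (10 and 10 when adjusted over the list alone). In the latter, Tnfrsf13b (0.84 ± 0.10) and the semaphorin gene Sema7a (0.68 ± 0.09) were higher. Neither list was called in camera with an estimated correlation (adjusted p = 0.37 and 0.29). With the preset correlation activation surface proteins were called lower without replicate 1 or 4 of anti-IgD with vehicle or replicate 3 of anti-IgD with PF-303 (medians from -0.08 to -0.05).

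PF-303 thus left 2195 genes higher and 1146 lower in stimulated cells, 41 and 65 of them by at least 2-fold. With the position code's row as a block the total was 1721 in place of 3341, and after shifting arrays to one median 1281 were higher and 1691 lower. Of the 1926 genes raised by anti-IgD in vehicle-treated mice 1015 were lower with PF-303, and of the 3392 lowered 1826 were higher. Independent calls would give 199 and 670. Both contrasts use the arrays of anti-IgD with vehicle, so noise in these arrays can add to the overlap. When these arrays were split between the contrasts, the means over splits were 666 and 1130 genes, where independent calls would give 112 and 358.

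Without anti-IgD, PF-303 lowered a small set of early response genes. Egr1 went from 611.4 ± 153 (n = 4) to 107.7 ± 19.0 (n = 5), a log2 fold change of -2.32 ± 0.16 (adjusted p = 1.1e-08), and Egr3 from 964.2 ± 139 to 220.7 ± 21.2 (-2.04 ± 0.14). Fos, a subunit of AP-1, fell by 2.19 ± 0.38, from 232.5 ± 72.05 to 39.5 ± 19.1. Nr4a1 (-1.54 ± 0.14), Egr2 (-1.48 ± 0.13), Nfkbid (-1.23 ± 0.16), Myc (-0.96 ± 0.13, adjusted p = 1.4e-04) and Cd83 (-0.67 ± 0.12) were lower too. Egr2 fell to a signal of 11.7, below the filter level, and its fold change was -2.30 with an offset of 1 and -0.73 with 64. H3f3b, a gene of the histone variant H3.3, fell by 1.76 ± 0.15 (adjusted p = 2.7e-07). Btk (0.08 ± 0.07), Klf2 (0.02 ± 0.12), S1pr1 (-0.01 ± 0.11), Nfkbia (-0.02 ± 0.11), Cd86 (-0.06 ± 0.09), Cd69 (0.18 ± 0.15), Ccl4 (0.12 ± 0.19), Ccl3 (-0.42 ± 0.18) and Irf4 (-0.42 ± 0.12) did not pass the test. Irf4 was called without replicate 2 of PBS with vehicle (-0.52).

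Rises were small, none above 0.69. Among them were Mgst1, which encodes a microsomal glutathione transferase (0.65 ± 0.14, adjusted p = 0.022), Tent5a (0.54 ± 0.12), Ifit1bl1 (0.52 ± 0.11) and Vpreb3 (0.48 ± 0.10). The call of each of these 4 was lost on leaving out one or another of the PBS arrays, every one of which ended at least 1 of these calls. Values then ranged from 0.50 to 0.65 for Mgst1, from 0.49 to 0.56 for Tent5a, from 0.39 to 0.52 for Ifit1bl1 and from 0.41 to 0.48 for Vpreb3. The call of Fos was lost without the 6 arrays of high spike-in signal, where its value was -2.08.

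Lists of early and growth genes were lower in these unstimulated cells. Of 26 immediate early genes 7 were lower, and 11 lower and 2 higher when adjusted over the list alone. Of 49 ribosome biogenesis genes 9 were lower (31 when adjusted over the list alone), with Nolc1 at -0.58 ± 0.08 and Gnl3 at -0.53 ± 0.07. Of 36 genes of MYC-linked growth metabolism 3 were lower (17 lower and 1 higher when adjusted over the list alone). Of 24 NF-kB targets 3 were lower (7 when adjusted over the list alone), among them Nfkbid and Cd83, and of 17 calcium-NFAT genes 4 (6 when adjusted over the list alone). These 5 lists were lower with an estimated correlation (adjusted p = 1.8e-05, 1.0e-05, 7.6e-04, 0.0097 and 0.0012 in this order). The calcium-NFAT list had a median of -0.06 and a mean of -0.34, and 8 of its 17 genes are on another list. Its lower members include Egr2, Egr3 and Nr4a1, which are also immediate early genes. Its call is therefore not separate from that of the immediate early list. Of 15 MAPK feedback genes 1 was lower, Egr1, and of 35 receptor signalling components 1, Vav3 (-0.66 ± 0.13). Of 25 activation surface proteins 1 was lower, Cd83 (3 when adjusted over the list alone), and of 31 FOXO and quiescence genes 0 were called (3 higher when adjusted over the list alone). None of these 4 lists was called with an estimated correlation (adjusted p = 0.16, 0.61, 0.30 and 0.28). With the preset correlation, MAPK feedback genes were called lower without replicate 3 of PBS with vehicle (median -0.07) and activation surface proteins without replicate 3 of PBS with PF-303 (-0.05). The Vav3 call was lost in a fit of only the PBS groups and with the position code's row as a block.

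In all, 7 genes were higher and 70 lower with PF-303 in unstimulated cells, and 10 of the latter fell at least 2-fold. Of the 70 lower genes 60 were also lower with PF-303 in stimulated cells, where independent calls would give 7.22. Of the 7 higher genes 6 were also higher there (1.38 for independent calls). These contrasts share no arrays, but both use the same estimate of spread for each gene, which can add to the overlap. The total of 77 was 42 with the position code's row as a block, 28 in a fit of only the PBS groups, 183 with array weights, 43 without the arrays of high spike-in signal and 154 with spike-in signal as a covariate. It was 49 without replicate 1 of PBS with vehicle, and 51 and 42 without replicates 1 and 4 of PBS with PF-303.

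Anti-IgD still acted strongly in PF-303-treated mice. Egr1 rose by 4.82 ± 0.15 (adjusted p = 2.4e-16), from 107.7 ± 19.0 to 3506 ± 697 (n = 5 each), Egr2 by 4.76 ± 0.13, from 11.7 ± 2.98 to 733.3 ± 67.5 (with a size that depends on the offset, 5.88 with 1 and 3.39 with 64), Egr3 by 3.81 ± 0.14 and Nr4a1 by 3.78 ± 0.13. Cd83 (2.16 ± 0.12), Irf4 (2.07 ± 0.11), Myc (1.75 ± 0.12), Cd86 (1.52 ± 0.09), Ccl3 (1.21 ± 0.17), Ccl4 (1.02 ± 0.18) and Nfkbid (0.77 ± 0.15) rose as well. Ccl3 began at a signal of 1.92, below the filter level, and its rise was 3.52 with an offset of 1 and 0.44 with 64. The largest falls were those of Rflnb (-1.95 ± 0.14), Neurl3 (-1.74 ± 0.13), Tent5a (-1.65 ± 0.11) and the kinase gene Sgk1 (-1.64 ± 0.14), and Klf2 fell by 0.68 ± 0.11. Btk had a value of -0.10 ± 0.07 (adjusted p = 0.29) and Nfkbia of -0.20 ± 0.10 (adjusted p = 0.13). S1pr1 rose by 0.31 ± 0.10 (adjusted p = 0.022), a call lost without replicate 4 of PBS with PF-303 (0.25), without replicate 1 of anti-IgD with PF-303 (0.27) and without the arrays of high spike-in signal (0.16).

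Growth and early genes rose here too. Of 49 ribosome biogenesis genes 48 rose, with a median of 0.76 (Gnl3 1.95 ± 0.07, Nolc1 1.49 ± 0.08), and of 36 genes of MYC-linked growth metabolism 30 rose and 2 fell (Srm 1.61 ± 0.09, Slc7a1 1.22 ± 0.08). Of 26 immediate early genes 17 rose and 3 fell, with Btg2 at -0.72 ± 0.09. Of 15 MAPK feedback genes 6 rose (8 when adjusted over the list alone), as did Plaur (1.42 ± 0.10), and 1 fell. Of 25 activation surface proteins 12 rose and 4 fell (5 when adjusted over the list alone), with the PD-L2 gene Pdcd1lg2 at 2.35 ± 0.10. Of 31 FOXO and quiescence genes 20 fell and 7 rose (Ypel3 -1.20 ± 0.07, Irs2 3.10 ± 0.12). With an estimated correlation the FOXO list was lower (adjusted p = 0.046) and the others higher (adjusted p = 4.2e-06, 2.8e-04, 9.2e-05, 0.0080 and 0.046 in this order).

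Of 17 calcium-NFAT genes 6 rose and 4 fell. Their median was -0.01, their mean 0.82 and the camera test placed the list higher (adjusted p = 0.046 with an estimated correlation), so median and test differ in sign. Of 24 NF-kB targets 8 rose and 7 fell (9 and 8 when adjusted over the list alone), with a median of 0.04, and the list was not called (adjusted p = 0.86 with an estimated correlation). Irf4 and Cd83 rose among them, and Bcl3 (-1.24 ± 0.12) and the stress gene Gadd45b (-0.60 ± 0.10) fell. Of 35 receptor signalling components 9 rose and 6 fell, with Fyn at 1.80 ± 0.12 and Syk at -1.03 ± 0.09. Their median was -0.07 and their mean 0.06, which differ in sign, and the list was not called (adjusted p = 0.95 with an estimated correlation).

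In PF-303-treated mice 1634 genes were higher and 2120 lower with anti-IgD, 202 and 78 of them by at least 2-fold. After shifting arrays to one median 1866 were higher and 1767 lower. Of the 1926 genes raised and 3392 lowered in vehicle-treated mice, 1251 and 1835 were called in the same direction. Independent calls would give 283 and 647. No array is shared between these 2 contrasts, but both use the same estimate of spread for each gene, which can add to the overlap. The Cd69 call (0.37 ± 0.14, adjusted p = 0.044) was lost without replicate 1 of PBS with vehicle, replicate 2 of anti-IgD with vehicle, replicate 2, 3, 4 or 5 of PBS with PF-303, or replicate 1, 2, 3 or 5 of anti-IgD with PF-303, with values from 0.33 to 0.39. Its value was 0.20 with the position code's row as a block and 0.20 without the arrays of high spike-in signal.

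**Figure D3:**
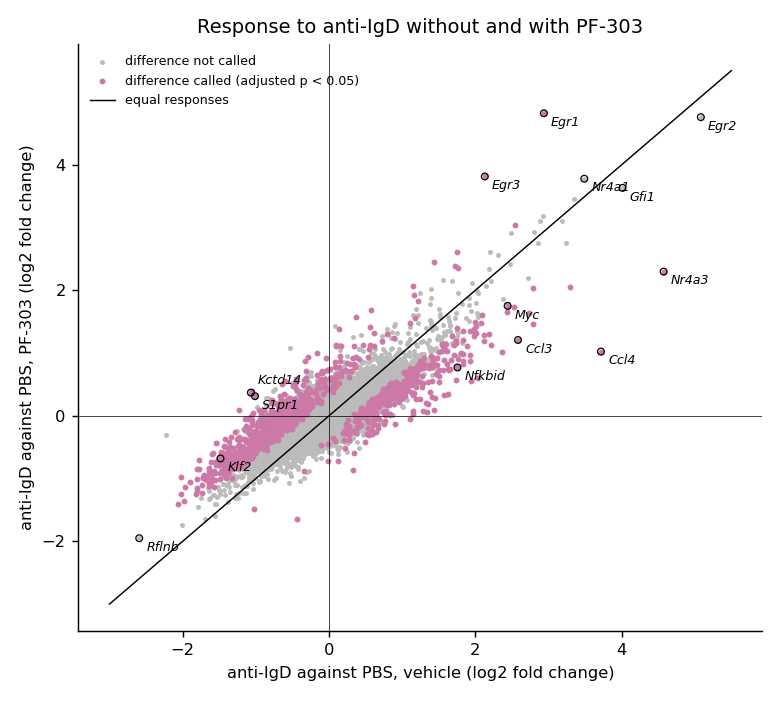
Log2 fold change with anti-IgD in vehicle-treated mice (horizontal axis) and in PF-303-treated mice (vertical axis), 1 point per gene, with pink for the 1081 genes whose responses differed and a line for equal responses. Ccl4 lay below the line (3.72 against 1.02), and S1pr1 (-1.01 against 0.31) and Kctd14 (-1.07 against 0.37) above it.

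The response to anti-IgD differed between the treatments for 1081 genes, with a positive difference (PF-303 minus vehicle) for 736 and a negative one for 345. After shifting arrays to one median the balance turned, with 344 positive and 683 negative. Differences were negative for Ccl4 (-2.69 ± 0.26, adjusted p = 3.9e-06), Nr4a3 (-2.28 ± 0.26), Tmem97, which encodes the sigma-2 receptor (-1.44 ± 0.21), and Ccl3 (-1.37 ± 0.26). Signals of Nr4a3 (9.96 in PBS with PF-303) and Ccl3 (8.45 and 1.92 in the PBS groups) began below the filter level, so the sizes of these differences depend on the added 16 and give no order. Cd69 (-1.001 ± 0.21), Nfkbid (-0.98 ± 0.23) and Myc (-0.69 ± 0.18) also rose less under PF-303. Differences were positive for Egr1 (1.88 ± 0.22), Egr3 (1.68 ± 0.20), Kctd14 (1.44 ± 0.13, adjusted p = 2.7e-06), Arhgef1 (1.32 ± 0.36), S1pr1 (1.32 ± 0.15), Klf2 (0.80 ± 0.17) and Btk (0.43 ± 0.10). Egr1 and Egr3 began from lower signals under PF-303, as given above. Egr2 (-0.32 ± 0.19), Nr4a1 (0.29 ± 0.20), Irf4 (-0.07 ± 0.16), Cd83 (0.47 ± 0.17), Cd86 (-0.40 ± 0.13) and Nfkbia (-0.27 ± 0.15) did not pass the test of the difference.

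Several of these calls rest on the settings. Those of Nr4a3 and Ccl3 were lost with an offset of 1 (-1.52 and -0.64), those of Myc (-0.74) and Nfkbid (-1.001) with the position code's row as a block, and that of Btk with that block (0.45) and after shifting arrays to one median (0.31). Arhgef1 lost its call without replicate 5 of anti-IgD with vehicle (1.203), and without the arrays of high spike-in signal its value was 0.63. Egr2 was called with an offset of 64 (-1.01) and had a value of 0.48 with 1, and Cd86 without replicate 2 of anti-IgD with vehicle (-0.47) or replicate 3 of anti-IgD with PF-303 (-0.46). The total of 1081 was 292 with the position code's row as a block and 716 without the arrays of high spike-in signal.

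Some responses turned around. In 33 genes the RNA fell with anti-IgD in vehicle-treated mice and rose in PF-303-treated mice, with each response and the difference called, and in 6 genes the reverse held. These counts were not taken with arrays shifted to one median. The 33 include Kctd14 (-1.07 ± 0.10 and 0.37 ± 0.09), S1pr1 (-1.01 ± 0.12 and 0.31 ± 0.10) and Sema7a (-0.46 ± 0.10 and 0.47 ± 0.09). The rise of S1pr1 under PF-303 was not called without replicate 4 of PBS with PF-303 (0.25), replicate 1 of anti-IgD with PF-303 (0.27) or the arrays of high spike-in signal (0.16). Ciita, the transactivator of MHC class II genes and named here after its values were seen, belongs to them (-0.47 ± 0.12 and 0.50 ± 0.11). The 6 include the kinase gene Pim1 (0.34 ± 0.10 and -0.86 ± 0.09), Gadd45b (0.35 ± 0.12 and -0.60 ± 0.10) and the adhesion molecule gene Icam1 (0.61 ± 0.09 and -0.28 ± 0.08).

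Among the lists, the difference was negative for ribosome biogenesis, with 17 of 49 lower (28 when adjusted over the list alone; Wdr43 -0.53 ± 0.10), for NF-kB targets, with 8 lower and 1 higher of 24 (10 and 4 when adjusted over the list alone; Rel -0.95 ± 0.13, Icam1 -0.89 ± 0.11), and for MYC-linked growth metabolism, with 9 of 36 lower (13 lower and 1 higher when adjusted over the list alone; Hk2 -1.08 ± 0.14, Mthfd2 -0.97 ± 0.14). It was positive for FOXO and quiescence genes, with 12 higher and 1 lower of 31 (17 higher when adjusted over the list alone; Cdkn1b 0.99 ± 0.12). These 4 lists were called with an estimated correlation (adjusted p = 1.3e-04, 0.013, 0.016 and 0.013 in this order). Receptor signalling components had 12 of 35 higher (17 when adjusted over the list alone; Dok3 1.04 ± 0.17, Rasgrp3 0.93 ± 0.14), and their call (adjusted p = 1.1e-06) was lost with an estimated correlation (adjusted p = 0.059 with an estimated correlation). Immediate early genes had 4 higher and 5 lower of 26, activation surface proteins 4 higher and 6 lower of 25 (8 and 8 when adjusted over the list alone), calcium-NFAT genes 1 and 1 of 17 (3 higher when adjusted over the list alone), and MAPK feedback genes 3 higher of 15, with Dusp6 at 0.82 ± 0.13. Median and mean differed in sign for MAPK feedback (-0.08 and 0.12) and calcium-NFAT genes (-0.05 and 0.04). None of these 4 was called (adjusted p over all lists from 0.52 to 0.93 with an estimated correlation).

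**Figure D4:**
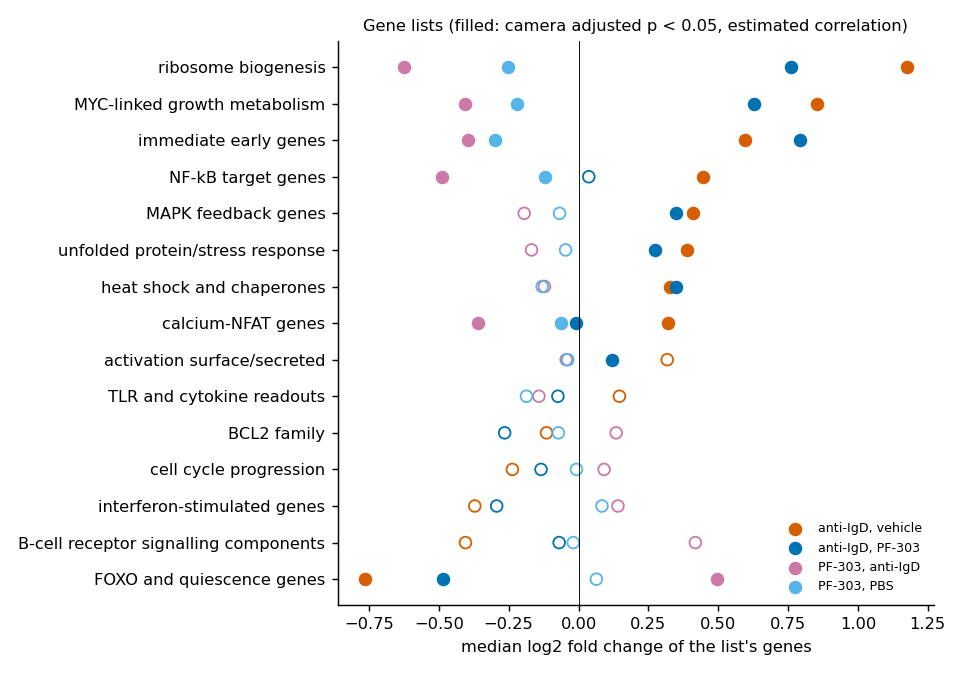
Median log2 fold change of the pathway lists in 4 contrasts, with filled points for lists called by camera at an adjusted p under 0.05 with an estimated correlation. Ribosome biogenesis rose with anti-IgD in vehicle-treated mice (median 1.17) and was lower with PF-303 in stimulated cells (-0.63) and in unstimulated cells (-0.25).

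The share of the response that remained under PF-303 was given for the genes that anti-IgD changed at least 2-fold in vehicle-treated mice. For the 392 raised genes the median share was 67.0% ± 2.24 (jackknife SE), with quartiles of 54.2% and 81.1%, and 343 of them responded less under PF-303. For the 401 lowered genes it was 57.3% ± 3.57, with quartiles of 46.2% and 70.5%, and 392 responded less. Still 370 of the raised and 366 of the lowered genes were called in PF-303-treated mice. These genes were chosen by their response in vehicle, which lowers the share. With genes chosen on part of the vehicle arrays and measured on the rest, the mean share was 69.6% for raised and 60.5% for lowered genes. With the position code's row as a block the values were 63.3% and 53.1%. These shares set each response against its own PBS group. Set against the PBS level of vehicle-treated mice, a choice made after the results were seen, they were 50.3% ± 2.10 and 49.8% ± 3.37.

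Shares were also taken for the lists, where the lower PBS level of raised genes under PF-303 enlarges the share. NF-kB targets kept 44.8% ± 4.67 of their summed rise (15 genes), activation surface proteins 64.9% ± 4.39 (13), ribosome biogenesis 70.03% ± 2.56 (48), MYC-linked growth metabolism 71.8% ± 4.31 (28) and immediate early genes 90.6% ± 3.65 (14). The immediate early genes Egr2, Nr4a3 and Maff had signals of 11.7, 9.96 and 3.85 in PBS with PF-303, below the filter level. The share of their list thus depends on the added 16, and list shares were not taken at another offset. Calcium-NFAT genes kept 99.02% ± 4.40 (8) and MAPK feedback genes 134% ± 7.48 (7), where Egr1 is a member. Egr2, Egr3 and Nr4a1 are on both the calcium-NFAT and the immediate early list. As ratios of sums, these shares weigh the largest responses most. The median raised member kept 43.9% for NF-kB targets, 47.7% for activation surface proteins, 68.9% for ribosome biogenesis and 73.8% for MYC-linked growth metabolism. It kept 81.8% for immediate early, 84.4% for calcium-NFAT and 111% for MAPK feedback genes. Among lowered genes, activation surface proteins kept 20.7% ± 10.97 (9), receptor signalling components 34.4% ± 7.32 (20), calcium-NFAT genes 50.7% ± 10.6 (6), FOXO and quiescence genes 55% ± 3.48 (20) and NF-kB targets 71.2% ± 7.99 (6). The 5 raised receptor signalling components kept 101% ± 8.67. Against the PBS level of vehicle-treated mice the raised NF-kB targets kept 16.7% ± 3.93, activation surface proteins 58.8% ± 3.54, ribosome biogenesis 45.9% ± 1.59, MYC-linked growth metabolism 48.6% ± 2.64, immediate early genes 58.4% ± 3.25, calcium-NFAT genes 62.96% ± 3.28, MAPK feedback genes 94.7% ± 4.07 and receptor signalling components 80.6% ± 6.65. The lowered activation surface proteins then kept 29.4% ± 11.8, receptor signalling components 32.1% ± 7.94, calcium-NFAT genes 53.2% ± 8.93, FOXO and quiescence genes 48.9% ± 3.10 and NF-kB targets 67.1% ± 3.93.

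**Figure D5:**
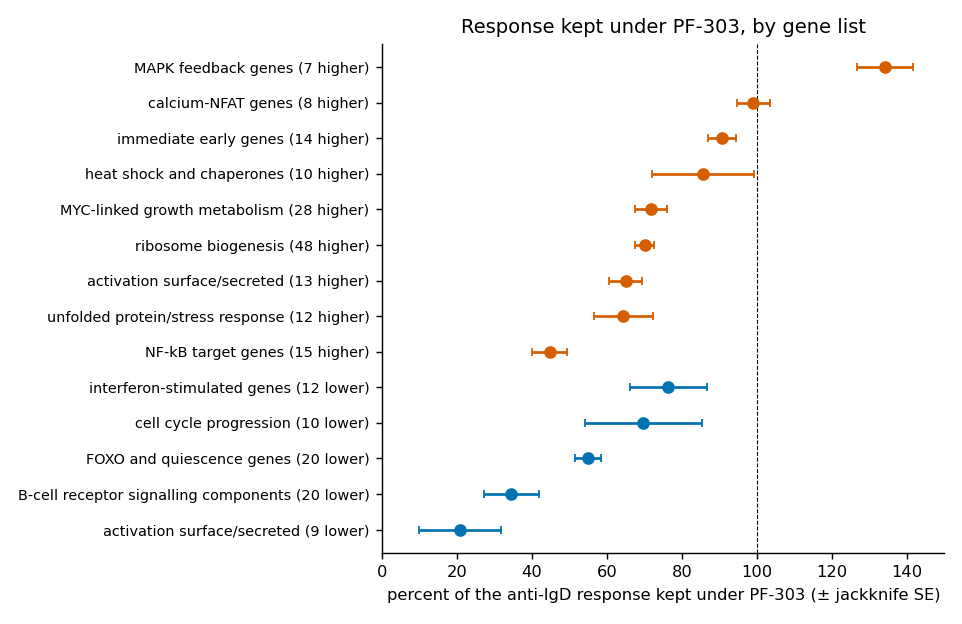
Percent of the anti-IgD response kept under PF-303 for the pathway lists, with members raised and members lowered in vehicle-treated mice shown apart. Only sets of at least 7 members are shown. Bars are jackknife SE, and each response is set against its own PBS group. Raised NF-kB targets kept 44.8% and raised immediate early genes 90.6%, and 16.7% and 58.4% when set against the PBS level of vehicle-treated mice.

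Some markers of B-cell subsets were called. As lists, follicular markers and those of marginal zone and B1 cells did not pass camera for anti-IgD in vehicle (adjusted p = 0.11 and 0.66) or for PF-303 in stimulated cells (0.096 and 0.15). Of 14 follicular B-cell markers, 9 fell and 1 rose with anti-IgD in vehicle-treated mice (10 fell when adjusted over the list alone), and 5 were higher and 1 lower with PF-303 in stimulated cells (8 higher when adjusted over the list alone). Cd79b, a chain of the receptor complex, went from 7181 ± 2114 to 3264 ± 246 (-1.09 ± 0.23, adjusted p = 4.0e-04). With PF-303 it was higher by 0.75 ± 0.22 in stimulated cells. Both calls were lost with the position code's row as a block. The highest signal on an array was 14618 to 20951 in the 6 arrays of high spike-in signal and 6862 to 12018 in the others. Anti-IgD with vehicle held none of the 6, and the SD of Cd79b was larger in PBS with PF-303 (2791) and anti-IgD with PF-303 (1157). Differences between arrays may thus add to the size of these changes. Ms4a1, which encodes CD20, had a value of -0.57 ± 0.26 (adjusted p = 0.071), and was called without replicate 1 (-0.74) or 2 (-0.68) of PBS with vehicle. Of 13 marginal zone and B1 markers 7 fell and 3 rose with anti-IgD in vehicle, and 7 were higher with PF-303 in stimulated cells. Mzb1, a chaperone gene of antibody-forming and marginal zone B cells, was lower by 1.23 ± 0.12 and higher by 0.72 ± 0.11. Under PF-303 anti-IgD raised 2 and lowered 4 follicular markers and raised 5 and lowered 5 marginal zone markers (6 lowered when adjusted over the list alone). The response differed for 1 and 3 of them (4 and 5 when adjusted over the list alone). In unstimulated cells 0 of either list were called. The follicular list was called higher for the difference between responses (adjusted p = 0.017), which was lost without replicate 4 of PBS with vehicle (median 0.30) and with the estimate (adjusted p = 0.63 with an estimated correlation).

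Of 9 germinal centre markers 3 fell and 1 rose with anti-IgD in vehicle, with Bcl6 at -0.57 ± 0.16 (call lost after shifting arrays to one median, -0.40), and of 11 plasma cell markers 3 fell and 2 rose. Over all genes, 3392 of 11106 fell and 1926 rose in this contrast, so falls in these lists were about as frequent as elsewhere. Of 10 dendritic cell markers 3 fell and 1 rose, with Bcl11a at -0.81 ± 0.11. The signal of Bcl11a in PBS with vehicle was 1974, against a list median of 28.7, so its fall does not stand for the list. A change of a marker here need not come from the cell type under which it is listed. Of 9 NK-cell markers 1 rose, Tbx21, a transcription factor gene also expressed in activated lymphocytes (2.12 ± 0.18), and 1 fell, and of 4 stromal and endothelial markers 2 fell, Pecam1 by 1.38 ± 0.17. Of 22 macrophage markers 2 rose and 1 fell, and of 3 mast cell and basophil markers 1 rose. Of 10 T-cell markers 1 rose, of 8 neutrophil markers 1 fell, and of 10 erythroid and 7 platelet markers 0 were called. With PF-303 in unstimulated cells 0 genes of these 11 lists were called over all genes. None of the 13 marker lists was called in camera with an estimated correlation in any contrast. The erythroid list, with a median of -0.52 for PF-303 in unstimulated cells, had an adjusted p of 0.013 that was lost with the estimate (adjusted p = 0.51 with an estimated correlation) and without replicate 3 of PBS with vehicle (median -0.13). With the preset correlation some marker lists were called when 1 array was left out. For PF-303 in unstimulated cells these were macrophage markers without replicate 4 of PBS with vehicle (median -0.20), neutrophil markers without that array (-0.25) or replicate 3 of PBS with PF-303 (-0.31), and follicular markers without the latter array (-0.11). For PF-303 in stimulated cells and for the difference, macrophage markers were called lower without replicate 5 of anti-IgD with vehicle (-0.32 and -0.24). Follicular markers were called without replicate 1 of PBS with vehicle for anti-IgD in vehicle (-0.64), and without replicate 4 of PBS with vehicle for PF-303 in stimulated cells (0.31). Without the arrays of high spike-in signal, macrophage (-0.33) and neutrophil markers (-0.29) were called lower with PF-303 in unstimulated cells.

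Genes of phagocytes were measured in every group. Cybb, a subunit of the phagocyte NADPH oxidase also expressed in B cells, had signals of 2834 ± 632 in PBS with vehicle and 2473 ± 290 in PBS with PF-303 (-0.18 ± 0.13, adjusted p = 0.70). The lysozyme gene Lyz1 had 1996 ± 138 and 2184 ± 634 (0.08 ± 0.28, adjusted p = 0.95). The neutrophil genes S100a8 and S100a9 had 183.9 ± 105 and 124.3 ± 79.3 in PBS with vehicle and 91.5 ± 52.9 and 46.1 ± 24.5 in PBS with PF-303 (-0.81 ± 0.42 and -1.11 ± 0.45, adjusted p = 0.51 and 0.36).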

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

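Of the tests in this part, those of array brightness, handling, BTK-dependent signalling without antigen, the scaling of arrays and low signal were chosen after the results were seen, as were the fits with the spike-in covariate, without the 6 arrays of high spike-in signal and with arrays shifted to one median. In groups of 4 or 5 arrays, the highest or lowest array was set apart when its gap to the nearest other, as a share of the range of the group, passed Dixon's critical value. Chance sets apart about 1 in 20 groups, and 26 of 476 groups of values were set apart.

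With anti-IgD and PF-303, replicate 1 was the highest array for Dusp6 (0.793), Gbp2 (0.820), Gbp3 (0.912), Arhgef1 (0.754) and the 3' to 5' ratio of Gapdh (0.895). Replicate 2 was the lowest for S1pr4 (0.731). Replicate 3 was the highest for Cd79b (0.738) and Gadd45b (0.8292) and the lowest for Vav3 (0.745). Replicate 4 was the lowest for Cd69 (0.898) and the highest for Fos (0.719). With PBS and PF-303, replicate 1 was the highest for Ccl3 (0.930) and replicate 2 for Gnl3 (0.729). The latter array was the lowest for Icam1 (0.813). Replicate 3 was the highest for Irs2 (0.839), Maff (0.730) and Pecam1 (0.712). Replicate 4 was the lowest for S1pr1 (0.757) and Srm (0.890), and replicate 5 for Sgk1 (0.742). With PBS and vehicle, replicate 3 was the highest for Rasa3 (0.941) and Rflnb (0.881) and replicate 4 for Kctd14 (0.936). With anti-IgD and vehicle, replicate 1 was the lowest for Ppp3cc (0.876), replicate 2 the lowest for Sgk1 (0.960) and replicate 5 the highest for Tfrc (0.8294). The values in brackets are the share of the range taken by the gap.

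For 39 genes the responses to anti-IgD were called in opposite directions in the 2 treatments, and the difference between them was called too. Of these, 6 were higher in vehicle-treated and lower in PF-303-treated mice and 33 the reverse. Falls in vehicle among the 33 were as small as -0.25, where the median log2 fold change of all genes was -0.13. The balance of 33 and 6 was not taken with arrays shifted to one median. Probe sets with no symbol or several symbols, which the comparisons do not use, were lower more often than higher with PF-303 in stimulated cells (792 lower and 266 higher of 4113 tested).

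The first pattern is the lower level of 7 immediate early genes with PF-303 in unstimulated cells (Egr1, Fos, Egr3, Nr4a1, Egr2, Myc and Jun, median log2 fold change -1.54 ± 0.164, jackknife SE). RNA from other cells left by the CD23 selection was tested by a covariate made from 81 markers of other cell types, fixed as lists beforehand. With it the median was -1.58 ± 0.180, which argues against such RNA only as far as these markers follow it. Many of them were weak, with list medians in PBS with vehicle from 16.7 (T cell) to 90.7 (stromal and endothelial) against a filter level of 15.2. The score also held Cybb, which B cells express too, and Bcl11a and Tbx21, which moved with anti-IgD. It thus does not follow other cells alone. Macrophage markers were lower without the arrays of high spike-in signal (-0.33), and their most abundant genes Cybb and Lyz1 had signals of 2834 and 1996 in PBS with vehicle. Array brightness was argued against by the spike-in covariate, with which the median was -1.55 ± 0.132. Handling of the cells before lysis stays open, since the heat shock list had a median of -0.13 ± 0.101, which bears on heat and folding stress alone. The call of Fos was lost without the arrays of high spike-in signal (-2.08), which does not bear on handling. BTK-dependent signalling without added antigen stays open too. Of the 70 genes lower here 60 were lower in stimulated cells too (7.22 for independent calls), in other arrays. Any recurring effect of PF-303, through BTK or not, would give such an overlap, so it cannot decide this.

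The second pattern is the excess of lower genes with anti-IgD in vehicle-treated mice (1926 higher and 3392 lower). Array brightness was argued against, since 36.1% of calls were higher with the spike-in covariate, as against 36.2% without it. The scaling of each array stays open. Shifting arrays to one median took the median log2 fold change of all genes from -0.13 to 0.04 and the share of higher calls to 55.99%, but such a shift moves all genes alike, so by construction the share had to rise and its turn does not show the cause. A change in the total RNA of stimulated cells is a biological explanation that scaled signals cannot test and that stays open.

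The last pattern is the fall of unnamed probe sets with PF-303 in stimulated cells (74.9% of their calls lower). Low signal was argued against, as unnamed probe sets lay below named ones of similar mean signal by 0.178 ± 0.0276 (difference -0.178, jackknife SE). Array brightness was argued against, with 71.8% lower (641 lower and 252 higher) under the spike-in covariate. No biological explanation was tested.

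Other splits of the arrays into groups of the same sizes were fitted to see whether chance gives as much. For anti-IgD in vehicle-treated mice 1 of 35 splits, the real one, gave as many genes (5318, highest other 9). For PF-303 in stimulated cells it was 1 of 100 splits (3341, highest other 1986), and for anti-IgD in PF-303-treated mice 1 of 100 (3754, highest other 11). Chance is unlikely to give these 3 counts. For PF-303 in unstimulated cells 2 of 100 splits gave as many genes as the real one (77), so chance is unlikely at this share, but the other split gave 647 genes. It set the 4 PBS arrays of high spike-in signal against the 5 others and points to a structure of the samples, and with the spike-in covariate the count was 154. For the difference between responses 2 of 100 splits gave as many (1081, highest other 1449), where the PBS labels were redrawn and the anti-IgD arrays kept their groups.

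For the number of lists called with the preset correlation, chance is not excluded. The counts as large were 6 of 35 splits for anti-IgD in vehicle (12 lists, highest other 14), 25 of 100 for PF-303 in stimulated cells (10, highest other 14), 28 of 100 for PF-303 in unstimulated cells (8, highest other 13), 8 of 100 for anti-IgD under PF-303 (10, highest other 12) and 54 of 100 for the difference (6, highest other 16). With an estimated correlation few splits gave as many lists: 1 of 35 (9 lists, highest other 2), 1 of 100 (6, highest other 2), 2 of 100 (5, highest other 5), 1 of 100 (9, highest other 1) and 1 of 100 (4, highest other 3) in this order. These ranks make chance less likely but cannot exclude it. For PF-303 in unstimulated cells another split gave as many lists as the real one. List calls that hold with an estimated correlation therefore rest on firmer ground than those that need the preset one.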

How the results depend on the processing

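The spike-in covariate, the fits without the 6 arrays of high spike-in signal and without the 2 arrays of highest Gapdh 3' to 5' ratio, the shift of arrays to one median and the share kept against the vehicle PBS level are tests chosen after the results were seen. Counts A to E are the genes changed by anti-IgD in vehicle (A), PF-303 in stimulated cells (B), PF-303 in unstimulated cells (C) and anti-IgD under PF-303 (D), and those whose response differed (E). No call of a named gene or list changed direction in any alternative. The balance of higher and lower genes did turn with arrays shifted to one median, by construction, to 2772 and 2179 (A), 1281 and 1691 (B), 1866 and 1767 (D) and 344 and 683 (E). In all, 318 of 408 results of named genes and 103 of 140 of lists had the same call in each alternative run. Testing each probe set gave 10030, 6487, 141 and 6682 for A to D. These count probe sets, by construction, with several for some genes and with the 4113 that have no symbol or several, of which 630 were higher and 626 lower in A and 266 and 792 in B. At an adjusted p under 0.01 B, C and E were 2162, 35 and 413, and requiring a change of at least 2-fold gave 793, 106, 10, 280 and 60 for A to E, again by construction. C was 183 with array weights, 28 in a fit of only the 2 groups, 154 with the spike-in covariate and 43 without the arrays of high spike-in signal, where E was 716. With the row of the position code as a block B, C and E were 1721, 42 and 292. With a replicate block A to E were 5193, 3352, 115, 3933 and 978, and arrays of equal number in different groups shared little (mean correlation of their deviations 0.029 over 24 pairs, 7 of them over 0.1).

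The median share of the response kept, 67.0% for raised and 57.3% for lowered genes, was 63.3% and 53.1% with the row block, 68.0% and 59.1% with the replicate block, 61.3% and 62.1% with arrays shifted to one median, 63.7% and 53.0% for genes changed at least 1.5-fold and 79.5% and 64.9% at 4-fold. Set against the PBS level of vehicle-treated mice it was 50.3% and 49.8%. For raised genes it was 62.8% over all probe sets, 70.1% with the spike-in covariate and 69.6% for genes chosen on part of the vehicle arrays. For lowered genes it was 53.0% with an offset of 1 and 61.6% with 64. Leaving out 1 array at a time gave 4842 to 5386, 2844 to 3561, 42 to 106, 3374 to 3937 and 783 to 1155 genes, shares of 65.9% to 68.3% and 54.4% to 60.2%, and 45 to 50 list calls. C was 49 without replicate 1 of PBS with vehicle, and 51 and 42 without replicates 1 and 4 of PBS with PF-303. List calls over the 5 contrasts were 46, 33 with an estimated correlation, 56 with fry, which does not compare a list with other genes, 53 with quantile normalization, 49 with the mean of probe sets, 48 with the replicate block, 47 with the spike-in covariate, 50 without the arrays of high spike-in signal and 47 with arrays shifted to one median. Named-gene calls lost numbered 41 with the row block, 23 without the arrays of high spike-in signal and 171 over the fits that leave out 1 array, where 28 were gained. Except where construction is named, the cause of a moved value was not tested.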

Other observations

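The tests of the hypothesis below and the shares measured against the PBS level of vehicle-treated mice were chosen after the results were seen, and the lists described first were fixed before. Chaperone and stress genes moved with anti-IgD. Of 15 heat shock and chaperone genes 10 rose and 0 fell in vehicle-treated mice (11 rose when adjusted over the list alone), with the mitochondrial chaperonin gene Hspd1 at 0.92 ± 0.08 and Hsph1 at 0.91 ± 0.14, and 9 rose in PF-303-treated mice. The list was called higher in both (adjusted p = 0.030 and 0.036 with an estimated correlation). With PF-303 it had 5 lower members in stimulated cells and 1 in unstimulated cells, calls of the list that were lost (adjusted p = 0.14 in each with an estimated correlation). Of 22 genes of the unfolded protein and integrated stress response 12 rose and 1 fell in vehicle, with the transcription factor genes Ddit3 at 1.72 ± 0.09 and Atf4 at 0.80 ± 0.08 and the chaperone gene Pdia4 at -0.98 ± 0.13. Under PF-303 12 rose (14 rose and 2 fell when adjusted over the list alone), and the list was called in both (adjusted p = 0.030 and 0.046 with an estimated correlation). With PF-303 in stimulated cells 6 were lower and 1 higher, among them Ppp1r15a, a phosphatase subunit gene of the stress response (-1.38 ± 0.11), and the call of the list was lost (adjusted p = 0.12 with an estimated correlation). In unstimulated cells 0 passed over all genes (1 lower when adjusted over the list alone), and the responses differed for 3 genes of this list and 0 of the heat shock list.

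Interferon-stimulated genes fell in part: of 29, 12 fell and 0 rose with anti-IgD in vehicle and 13 fell under PF-303 (14 when adjusted over the list alone). The guanylate-binding protein genes Gbp3 (-1.64 ± 0.09 in vehicle and -1.32 ± 0.08 under PF-303) and Gbp2 (-1.05 ± 0.10 and -0.76 ± 0.09) were among them. The list calls were lost in both (adjusted p = 0.54 and 0.25 with an estimated correlation). With PF-303 7 were higher in stimulated cells and 0 in unstimulated cells, and the response differed for 1. Of 12 BCL2 family genes 2 rose and 5 fell in vehicle, with Bcl2l1, which encodes the survival protein BCL-XL, at 0.58 ± 0.15 and Bcl2 at -1.05 ± 0.15. Bcl2l1 was lower by 0.95 ± 0.14 with PF-303 in stimulated cells, where 2 members were higher and 2 lower. In unstimulated cells 0 were called, under PF-303 3 rose and 4 fell (6 fell when adjusted over the list alone), and the response differed for 3. The median of this list in vehicle (-0.11) and its test (higher) differed in sign. Of 33 cell cycle genes 10 fell and 3 rose in vehicle (9 fell when adjusted over the list alone), with E2f2 at -1.57 ± 0.15, the uracil glycosylase gene Ung at 1.93 ± 0.14 and Pcna at 0.87 ± 0.09. Falls in this list were about as frequent as over all genes, where 3392 of 11106 fell and 1926 rose. With PF-303 3 cell cycle genes were lower and 1 higher in stimulated cells and 0 in unstimulated cells. Under PF-303 4 fell and 3 rose, and the response differed for 1. Of 15 readouts of TLR and cytokine signals 3 rose and 2 fell in vehicle, 4 rose and 2 fell under PF-303 (Socs3 1.25 ± 0.29), and Pim1 alone was called with PF-303 in stimulated cells (-1.42 ± 0.09) and for the difference. This list was called lower with PF-303 in stimulated cells (adjusted p = 0.015) and unstimulated cells (adjusted p = 0.0069). Both calls were lost with the estimate (adjusted p = 0.29 and 0.25 with an estimated correlation), the first also without replicate 2 of anti-IgD with vehicle (median -0.07) and the second without replicate 2 of PBS with vehicle (-0.10). None of the BCL2, cell cycle and interferon lists was called with an estimated correlation in any contrast. Of the responses in vehicle, the raised heat shock genes kept 85.6% ± 13.6 under PF-303 and the raised stress response genes 64.4% ± 7.77. The lowered interferon genes kept 76.3% ± 10.3, cell cycle genes 69.7% ± 15.6 and BCL2 family genes 57.7% ± 17.4. Against the PBS level of vehicle-treated mice these shares were 59.98% ± 10.2, 50.8% ± 7.33, 60.7% ± 7.31, 57.3% ± 10.5 and 56.1% ± 14.5 in this order.

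A hypothesis for further work is that NF-kB target genes need BTK more than immediate early genes do in the first 2 h after crosslinking. The 15 raised NF-kB genes kept 44.8% of their response and the 14 raised immediate early genes 90.6%, a difference of 45.9 ± 3.44 points (jackknife SE). Of these, 0 genes are on both lists. The 6 lowered NF-kB targets, left out here, kept 71.2%. The errors run over arrays and do not measure the spread between genes of a list. In stimulated cells Irf4 and Cd83 of the NF-kB list had signals of 2268 and 4807 with vehicle and 1614 and 4202 with PF-303. Nr4a3 and Myc of the immediate early list had 1002 and 2883 with vehicle and 110 and 924.1 with PF-303. Single genes thus went against the list shares. The immediate early share also depends on the added 16. Immediate early genes start lower under PF-303, which by itself enlarges their kept response, so the share was also measured from the PBS level of vehicle-treated mice in both arms. It was then 16.7% ± 3.93 for NF-kB and 58.4% ± 3.25 for immediate early genes, and the difference of 41.6 ± 3.09 points may reflect a greater need for BTK. Effects of PF-303 that do not run through BTK could give such a gap too, and no test here tells these apart. The size of the response was tested for the NF-kB genes only. Each was set against 10 other raised genes of similar response, with each response measured from its own PBS group. The median difference in share was -34.7 ± 16.8 points, just beyond 2 standard errors, which argues against size as the source of the low NF-kB share. Immediate early genes were not matched in this way, so size as a source of the gap between the lists stays open. Timing was not tested, as cells were collected at 1 time. A fast and brief response could differ from a slow one without a difference in need.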
